A study of Homo sapiens with 15 samples.

How the data were processed

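Total RNA of 15 libraries from the A375 melanoma line was sequenced with an Illumina TruSeq preparation, in 5 groups of 3. The authors deposited 1 file per library with a log2 value per gene symbol, the log2 of a normalized count plus 1. Their processing notes name kallisto, DESeq2 and the GRCh38 build, without versions, settings or annotation release. Gene lists differ between the experiments, with 16768 symbols for the 9 vehicle and saracatinib libraries, 16295 for the 6 untreated libraries and 15703 in both. Size factors recomputed with the median of ratios within each experiment were 0.998 to 1.01. Over all 15 libraries they were 0.980 to 0.991 in the vehicle and saracatinib libraries and 1.035 to 1.045 in the untreated ones, as values scaled within each experiment would give. After undoing the log, each library summed to 14443918 to 16262759 normalized counts. For values of 0.3 to 6, 47.1% to 53.6% lay within 0.1 of a whole multiple of a step between them, against 20% by chance for 1 fixed step. The step was the one with the highest share in each library. The median share over the steps tried was 17.2% to 18.8%. Whole reads were therefore not recovered, no count-based test was run, and no counting interval is given.

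The samples were grouped by their titles. The genotype field of the 3 RAC1 P29S samples gives the empty vector, and the RAC1 level was checked against both. Replicate numbers do not pair libraries: correlations of residuals between libraries of the same number in different groups ranged from -0.0547 to 0.0125, so the fit holds the group alone.

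The design fixed before the data were examined assumed counts and a count-based test. With log2 values, limma 3.58.1 in R 4.3.3 was used in its place: a linear model with 1 mean per group, empirical Bayes with a mean-variance trend and robust estimation, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The 9 libraries shared 1 fit, the 6 untreated libraries another, and the difference of effects used all 15 libraries and the 13810 genes tested in both. Genes with a normalized count of at least 10 in at least 3 libraries were tested, 14410 and 14036 genes. The other choices made before the data were examined were the comparisons, the gene lists, the rule for named genes and most alternatives. Error values after ± are SE for fold changes and SD for levels.

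Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, for lists with at least 5 tested members, and again with a correlation estimated per list. The 28 lists included MAPK pathway output, AP-1 factors, SRF and MRTF targets, YAP and TEAD targets, melanocyte differentiation, the dedifferentiated state, NF-kB targets, interferon response, S phase, G2 and M phase, cholesterol synthesis, ATF4 targets, hypoxia, p53 targets, SRC family, matrix and integrins, TGF-beta response, MYC targets and receptor tyrosine kinases. They also included haematopoietic, fibroblast, epithelial, endothelial and neural crest markers, and mitochondrially encoded, ribosomal protein and histone genes.

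Genes are named by a rule. VAV1 and RAC1 are always given. For VAV1, saracatinib and RAC1 P29S, the 8 highest and 8 lowest log2 fold changes are named among genes with adjusted p under 0.05, a mean equivalent to at least 5 CPM in the higher group and no overlap between the libraries. From each list past the set test, or with at least 3 members past the threshold, up to 4 members with the smallest adjusted p qualify, of which the text prints some. For the remaining comparisons up to 5 per direction are named, and shared genes are ranked by the smaller absolute change. Clone and accession names were skipped, and some genes and 1 gene list are not reported here. Coordinates come from GENCODE release 29, in which 94.9% of tested symbols were found once.

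The opposite moves under saracatinib were compared with 100 simulations without an inhibitor effect. Alternatives were recomputed median-of-ratios, upper-quartile and total-count scaling, quantile normalization, 2 other filters, pseudocounts of 4 and 16, other sets of libraries in the fit, a replicate block, a test against a fold change of 1.5 and leaving out each library. The method was tested on simulated data with 200 changed genes per comparison. In the 4 comparisons of 2 groups, 87.8% to 89.8% of genes with a simulated 2-fold change and 36.7% (VAV1 with saracatinib) to 55.3% (saracatinib) of those with a 1.25-fold change were recovered, and unchanged genes made up 4.27% to 8.38% of the calls (6.71% for VAV1). For the difference of effects, 36 of 45 genes with a 2-fold and 8 of 42 with a 1.25-fold difference were recovered, and 6 of 13453 unchanged genes were called, so small differences between the effects were often missed there. In the data 15.8% to 43.7% of tested genes passed, a larger share than was changed in the simulations. The adjusted p depends on that share, so these rates need not carry over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.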

Results

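RNA sequencing measured gene expression in A375, an established human melanoma cell line with mutant BRAF, that carried an empty vector, VAV1 or RAC1 P29S. VAV1 is a guanine nucleotide exchange factor that activates GTPases such as RAC1, and RAC1 P29S is a recurrent activated form of RAC1 in melanoma. The series concerns transposon screens for resistance to MAPK pathway inhibitors, but no sample label names such an inhibitor. The 15 libraries form 5 groups of 3. In 1 experiment of 9 libraries, empty-vector cells received vehicle and VAV1 cells received vehicle or saracatinib, an inhibitor of SRC family kinases. In the other experiment, of 6 libraries, empty-vector and RAC1 P29S cells were untreated. The labels give no dose and no time, and no group combines the empty vector with saracatinib. The design text calls the 3 libraries of a group biological triplicates, without saying whether they came from separate transductions, so the p-values measure the spread between these cultures.

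Each library held 14443918 to 16262759 normalized counts after the log was undone. The number of reads behind them is not given, and whole reads could not be recovered from the values. Libraries of the same group correlated at 0.981 to 0.987 across genes, and libraries of different groups in an experiment at 0.942 to 0.967. In all, 14410 genes were tested in the vehicle and saracatinib libraries and 14036 in the untreated ones. Fold changes are differences of log2(normalized count + 1), which understate the change of genes with low counts.

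The transgenes went with the sample titles. VAV1 (chromosome 19, 6772714 to 6857366, GRCh38) lay at a log2 value of 2.22 ± 0.30 (SD, n = 3) in empty-vector cells with vehicle, 13.91 ± 0.04 in VAV1 cells with vehicle and 14.12 ± 0.03 in VAV1 cells with saracatinib. It was not listed in the table of the untreated libraries. RAC1 (chromosome 7, 6374523 to 6403977) lay at 14.93 ± 0.03 in the RAC1 P29S cells and at 11.88 ± 0.02 in their empty-vector controls, a difference of 3.05 ± 0.04 (SE, 8.28-fold, limma adjusted p = 1.90e-11). The genotype field of the 3 RAC1 P29S samples reads empty vector, against their titles. The groups follow the titles, and the RAC1 level separates them the same way. Values per gene symbol cannot tell a transgene from the endogenous gene, or the P29S form from wild type.

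**Figure D1:**
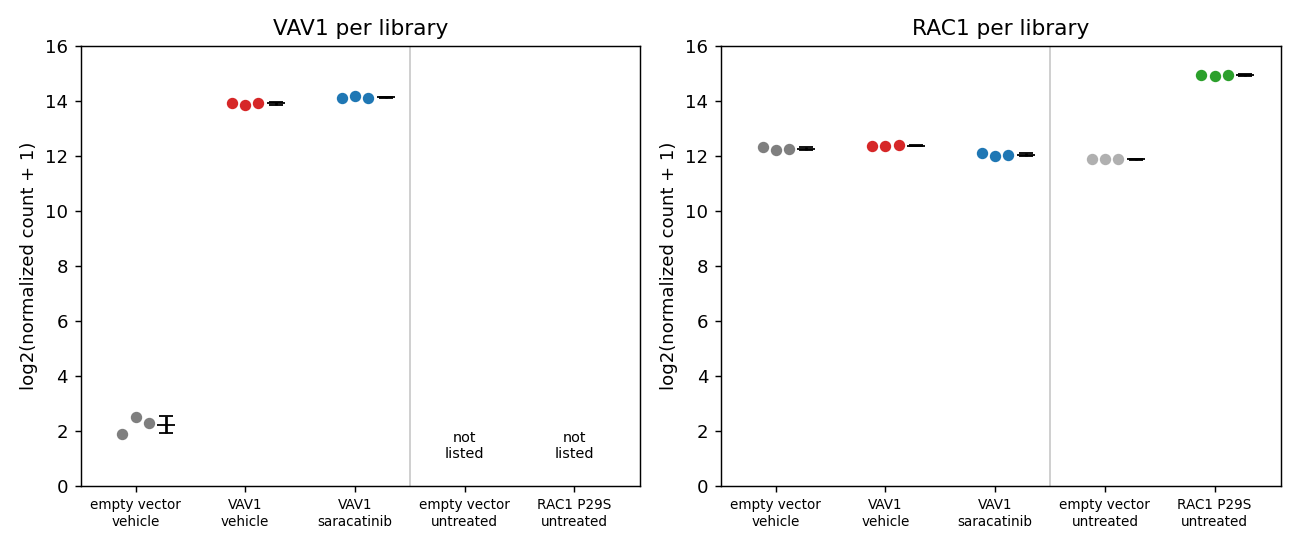
Log2(normalized count + 1) of VAV1 and RAC1 in each of the 15 libraries (points), with the group mean and SD (black bars, n = 3), for the 2 experiments. VAV1 lies near 13.91 and 14.12 in the VAV1 groups against 2.22 in their control, and RAC1 at 14.93 in the RAC1 P29S group against 11.88.

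The first comparison asks what VAV1 did to the transcriptome of vehicle-treated cells. VAV1 cells had higher expression of the peptidase gene MME, the membrane protein gene BASP1, the chloride channel gene ANO2, the G protein signalling regulator RGS4 and the kisspeptin precursor KISS1. BASP1 rose by 6.25 ± 0.13 on the log2 scale (SE, 75.9-fold), RGS4 by 6.10 ± 0.26 (68.4-fold), KISS1 by 6.09 ± 0.28 (68.0-fold), MME by 6.85 ± 0.68 (116-fold) and ANO2 by 6.18 ± 0.48. IGFN1, the cardiac troponin gene TNNT2 and SH3GL2, which encodes endophilin A1, rose by 5.85 ± 0.20, 5.70 ± 0.36 and 5.50 ± 0.17. Lower were the retinoid receptor RXRG, with a log2 fold change of -4.20 ± 0.28, the matrix gene HMCN1 (-3.83 ± 0.21), the phosphodiesterase PDE3A (-3.74 ± 0.29) and the ion exchanger SLC24A3 (-3.62 ± 0.34). The neural crest transcription factor TFAP2B (-3.56 ± 0.12), the extracellular superoxide dismutase SOD3 (-3.56 ± 0.27), FXYD3 (-3.55 ± 0.10) and HLA-DOA (-3.49 ± 0.30) were lower too. The highest limma adjusted p of these 16 genes was 0.000196, for MME. VAV1 itself was higher by 11.68 ± 0.11 (3291-fold, limma adjusted p = 3.43e-15). RAC1 was higher by 0.12 ± 0.05 (limma adjusted p = 0.0451), a call lost in 11 alternative settings.

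Targets of YAP and TEAD, of ATF4 and of MYC rose in VAV1 cells. Of 22 tested YAP and TEAD targets, 15 rose and 2 fell (15 and 2 adjusted over the list alone, median 0.82, camera adjusted p = 4.29e-06). ANKRD1 rose by 3.08 ± 0.08, CYR61 by 1.60 ± 0.05 and the receptor kinase AXL by 1.08 ± 0.05. Of 27 genes of the ATF4 integrated stress response, 24 rose and 2 fell (25 and 2 adjusted over the list alone, median 0.61, camera adjusted p = 1.97e-09). They include the serine synthesis gene PSAT1 (0.94 ± 0.05), the amino acid transporter SLC7A5 (0.84 ± 0.05), the folate enzyme MTHFD2 (0.87 ± 0.05) and TRIB3 (0.92 ± 0.06). Of 29 MYC targets, 21 rose and 0 fell (23 and 0 adjusted over the list alone, median 0.42, camera adjusted p = 2.35e-09), among them ODC1 (1.06 ± 0.07), TFRC (0.73 ± 0.04) and NPM1 (0.70 ± 0.04). These 3 lists also passed camera with an estimated correlation, at adjusted p = 0.0141, 0.0141 and 0.00994 in that order.

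Cytoskeletal, p53, G2 and M phase and cholesterol genes rose too, none of them past camera with an estimated correlation. Of 25 SRF and MRTF targets, 14 rose and 2 fell (14 and 3 adjusted over the list alone, median 0.21, camera adjusted p = 0.00518, and adjusted p = 0.103 with an estimated correlation), with VCL at 0.66 ± 0.05 and TPM1 at 0.72 ± 0.06. Of 23 p53 targets, 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.43, camera adjusted p = 0.00112, and adjusted p = 0.103 with an estimated correlation). The stress cytokine GDF15 rose by 4.02 ± 0.13, the cell cycle inhibitor CDKN1A by 0.74 ± 0.06 and the death receptor FAS by 1.23 ± 0.11. Of 30 genes of G2 and M phase, 17 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 0.00359, and adjusted p = 0.220 with an estimated correlation), with CDC20 at 0.51 ± 0.05. Of 24 cholesterol synthesis genes and SREBP2 targets, 11 rose and 4 fell (11 and 4 adjusted over the list alone, median 0.20, camera adjusted p = 0.0405, and adjusted p = 0.219 with an estimated correlation). SQLE rose by 0.56 ± 0.06.

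Genes induced by MAPK signalling, neural crest and melanocyte genes, and matrix genes fell in VAV1 cells. Of 20 genes of MAPK pathway output, 14 fell and 4 rose (4 and 15 adjusted over the list alone, median -0.51, camera adjusted p = 5.13e-05, and adjusted p = 0.0844 with an estimated correlation); this and the following counts over the list alone give higher members first. The pathway inhibitors SPRY4 and SPRY2 changed by -2.29 ± 0.07 and -1.82 ± 0.05, and the immediate early gene EGR1 by -2.30 ± 0.09. Of 18 neural crest and Schwann markers, 9 fell and 4 rose (4 and 9 adjusted over the list alone, median -1.04, camera adjusted p = 0.00518, and adjusted p = 0.0844 with an estimated correlation). Of 14 melanocyte differentiation genes, 6 fell and 2 rose (2 and 6 adjusted over the list alone, median -0.17, camera adjusted p = 0.0274, and adjusted p = 0.123 with an estimated correlation). The lineage factor SOX10 changed by -2.07 ± 0.04 and the receptor ERBB3 by -2.59 ± 0.05, while SOX9 rose by 4.11 ± 0.13 and MITF, the melanocyte master regulator, by 1.57 ± 0.11. Of 41 genes of extracellular matrix and integrins, 24 fell and 8 rose (8 and 25 adjusted over the list alone, median -0.54, camera adjusted p = 4.29e-06, and adjusted p = 0.219 with an estimated correlation). ITGB3 changed by -2.70 ± 0.05, TNC by -2.72 ± 0.06, TIMP3 by -1.51 ± 0.03 and SPARC by -1.11 ± 0.03. Of 13 mitochondrially encoded genes, 4 fell and 0 rose (0 and 9 adjusted over the list alone, median -0.48, camera adjusted p = 0.00432, and adjusted p = 0.567 with an estimated correlation). The share of counts from such genes was 1.21% ± 0.19 (SD, n = 3) with VAV1 and 1.66% ± 0.21 in the control.

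Some lists that did not pass as a whole held large changes in both directions. Of 26 genes of the dedifferentiated and invasive melanoma state, 12 rose and 6 fell (13 and 8 adjusted over the list alone, median 0.16, camera adjusted p = 0.0604, range 0.0415 to 0.0774 without 1 of the 9 libraries), with EGFR at 1.86 ± 0.08 and the growth factor NRG1 at 3.75 ± 0.16. Of 15 AP-1 transcription factors, 6 rose and 4 fell (8 and 5 adjusted over the list alone, camera adjusted p = 0.562), with JUN at 1.93 ± 0.09, FOSL2 at 2.01 ± 0.11, FOS at -1.75 ± 0.09 and MAF at -3.01 ± 0.18. Of 33 receptor tyrosine kinases and ligands, 16 rose and 10 fell (16 and 11 adjusted over the list alone, camera adjusted p = 0.213), with HBEGF at 2.88 ± 0.11, MET at 1.28 ± 0.05 and TGFA at -2.20 ± 0.05. Of 25 TGF-beta response genes, 8 rose and 7 fell (8 and 8 adjusted over the list alone, camera adjusted p = 0.917).

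In all, 6292 of 14410 genes passed limma at an adjusted p of 0.05, 3399 higher and 2893 lower with VAV1, and 1466 of them changed more than 2-fold. The libraries of the groups did not overlap for 7594 genes, where chance gives 10% of genes with 3 against 3. The camera call of the cholesterol list was lost without empty vector 2 (adjusted p = 0.0532), empty vector 3 (0.0585), VAV1 vehicle 1 (0.0527), VAV1 vehicle 3 (0.0516) and saracatinib 3 (0.0506), in a range of 0.0247 to 0.0585 over the 9 libraries, and with quantile normalization (0.0510, range 0.0408 to 0.0510 over the scalings). Reads of HLA genes can be shared between near-identical copies, so the value of HLA-DOA is uncertain.

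The next comparison asks what SRC inhibition did to VAV1 cells. Saracatinib raised the mucin gene MUC2 by 4.61 ± 0.45 on the log2 scale (SE, 24.5-fold), the prohormone convertase PCSK1 by 4.44 ± 0.13 (21.7-fold), the protease inhibitor A2M by 4.04 ± 0.24 and DMBT1 by 4.01 ± 0.18. The proline transporter SLC6A20 rose by 3.93 ± 0.79, the transcription cofactor CITED1 by 3.78 ± 0.31, the hyaluronan-binding CEMIP by 3.65 ± 0.07 and the proton pump subunit ATP6V0A4 by 3.58 ± 0.13. Lower were the keratin-associated KRTAP2-3 (-5.29 ± 0.46), tissue factor F3 (-2.70 ± 0.21) and ESM1 (-2.61 ± 0.10). The glutathione-degrading enzyme CHAC1 (-2.59 ± 0.13), ANKRD1 (-2.34 ± 0.08), the matricellular CTGF (-2.25 ± 0.07) and the ubiquitin ligase MARCH4 (-2.17 ± 0.27) were lower too. The highest limma adjusted p of these 15 genes was 0.00392, for SLC6A20, and reads of KRTAP2-3 can be shared with its close relatives. VAV1 itself differed by 0.22 ± 0.11 (limma adjusted p = 0.152), and RAC1 by -0.33 ± 0.05 (limma adjusted p = 7.80e-05). VAV1 passed in 4 alternative settings, and its libraries did not overlap, with log2 values of 13.86 to 13.94 with vehicle and 14.10 to 14.16 with saracatinib.

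Cell cycle and growth genes fell with saracatinib; counts over the list alone again give higher members first. Of 30 S phase genes and E2F targets, 28 fell and 0 rose (0 and 29 adjusted over the list alone, median -0.50, camera adjusted p = 4.64e-15), with RRM2 at -0.77 ± 0.04, UHRF1 at -0.74 ± 0.05 and the helicase subunit MCM7 at -0.59 ± 0.04. Of 30 genes of G2 and M phase, 26 fell and 1 rose (1 and 27 adjusted over the list alone, median -0.45, camera adjusted p = 5.73e-14), with CDC20 at -0.89 ± 0.05 and PLK1 at -0.67 ± 0.05. Of 29 MYC targets, 24 fell and 0 rose (0 and 25 adjusted over the list alone, median -0.38, camera adjusted p = 1.83e-11), with ODC1 at -1.26 ± 0.07. Of 27 ATF4 targets, 23 fell and 1 rose (1 and 23 adjusted over the list alone, median -0.87, camera adjusted p = 4.64e-15), with the amino acid synthesis genes ASNS, PSAT1 and PHGDH at -1.66 ± 0.07, -1.50 ± 0.05 and -1.12 ± 0.04. Of 22 YAP and TEAD targets, 16 fell and 2 rose (2 and 18 adjusted over the list alone, median -0.56, camera adjusted p = 3.13e-07), with CYR61 at -1.91 ± 0.05 and AXL at -1.08 ± 0.05. Of 25 SRF and MRTF targets, 16 fell and 1 rose (1 and 16 adjusted over the list alone, median -0.26, camera adjusted p = 3.94e-05), with TPM1 at -0.94 ± 0.06 and ACTB at -0.58 ± 0.04. All 6 lists passed camera with an estimated correlation too, the SRF and MRTF targets with the highest adjusted p, 0.0207.

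Sterol, pigment cell and interferon genes rose. Of 24 cholesterol synthesis genes and SREBP2 targets, 22 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.59, camera adjusted p = 1.69e-14). HMGCS1 rose by 1.57 ± 0.08, MSMO1 by 1.38 ± 0.08 and INSIG1 by 1.36 ± 0.06. Of 14 melanocyte differentiation genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.00196). GPNMB rose by 1.62 ± 0.05, ERBB3 by 0.78 ± 0.05 and SOX10 by 0.63 ± 0.04, and MITF changed by -1.09 ± 0.11. Of 27 type I interferon response genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 0.00324), with IRF9 at 1.17 ± 0.15 and STAT2 at 0.50 ± 0.08. With an estimated correlation camera gave these 3 lists adjusted p = 0.00295, 0.0346 and 0.0346.

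A further 10 lists passed the set test with the preset correlation and not with an estimated one. Of 26 genes of the dedifferentiated and invasive state, 14 fell and 3 rose (3 and 16 adjusted over the list alone, median -0.28, camera adjusted p = 0.00380, and adjusted p = 0.128 with an estimated correlation), including THBS1 at -1.90 ± 0.07 and AXL at -1.08 ± 0.05. Of 25 TGF-beta response genes, 13 fell and 6 rose (6 and 13 adjusted over the list alone, median -0.35, camera adjusted p = 0.0307, and adjusted p = 0.0907 with an estimated correlation). Of 18 SRC family kinases and substrates, 8 fell and 2 rose (2 and 9 adjusted over the list alone, median -0.29, camera adjusted p = 0.0187, and adjusted p = 0.148 with an estimated correlation), with CAV1 at -1.43 ± 0.06. MAPK pathway output moved up, with 10 of 20 higher and 4 lower (13 and 4 adjusted over the list alone, median 0.26, camera adjusted p = 0.00849, and adjusted p = 0.128 with an estimated correlation). The phosphatase DUSP4 rose by 1.02 ± 0.04 and PHLDA1 by 0.92 ± 0.04, and FOSL1 changed by -0.57 ± 0.04. Neural crest and Schwann markers had 8 of 18 higher and 2 lower (10 and 3 adjusted over the list alone, median 0.55, camera adjusted p = 0.00932, and adjusted p = 0.0599 with an estimated correlation), with FOXD3 at 1.54 ± 0.18. NF-kB targets and inflammatory cytokines had 7 of 23 higher and 2 lower (8 and 2 adjusted over the list alone, median 0.32, camera adjusted p = 0.00932, and adjusted p = 0.0599 with an estimated correlation), with IL24 at 2.39 ± 0.06. Matrix and integrin genes had 21 of 41 higher and 10 lower (21 and 10 adjusted over the list alone, median 0.19, camera adjusted p = 0.00250, and adjusted p = 0.306 with an estimated correlation), with the collagenase MMP1 at 2.72 ± 0.10.

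The remaining lists of this kind were hypoxia and glycolysis, ribosomal proteins and mitochondrially encoded genes. Hypoxia and glycolysis genes were higher in 10 of 25 cases and lower in 5 (11 and 5 adjusted over the list alone, median 0.08, camera adjusted p = 0.0251, and adjusted p = 0.0854 with an estimated correlation). Of 83 ribosomal protein genes, 33 were higher and 1 lower (34 and 1 adjusted over the list alone, median 0.10, camera adjusted p = 1.81e-05, and adjusted p = 0.435 with an estimated correlation). Of 13 mitochondrially encoded genes, 4 were higher and 0 lower (4 and 0 adjusted over the list alone, median 0.37, camera adjusted p = 0.00722, and adjusted p = 0.457 with an estimated correlation). Their share of counts was 1.70% ± 0.28 (SD, n = 3) with saracatinib against 1.21% ± 0.19 with vehicle. In all, 5381 genes passed limma, 2632 higher and 2749 lower, and 751 changed more than 2-fold, 543 of them higher. The camera call of the mitochondrial list was lost without saracatinib 1 (adjusted p = 0.0560, range 0.000243 to 0.0560 over the 9 libraries), and that of the TGF-beta list without VAV1 vehicle 1 (0.0592, range 0.0211 to 0.0592). Quantile normalization ended the camera calls of the hypoxia list (adjusted p = 0.0564, range 0.0211 to 0.0564 over the scalings) and of the SRC list (0.0654, range 0.0152 to 0.0654).

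**Figure D2:**
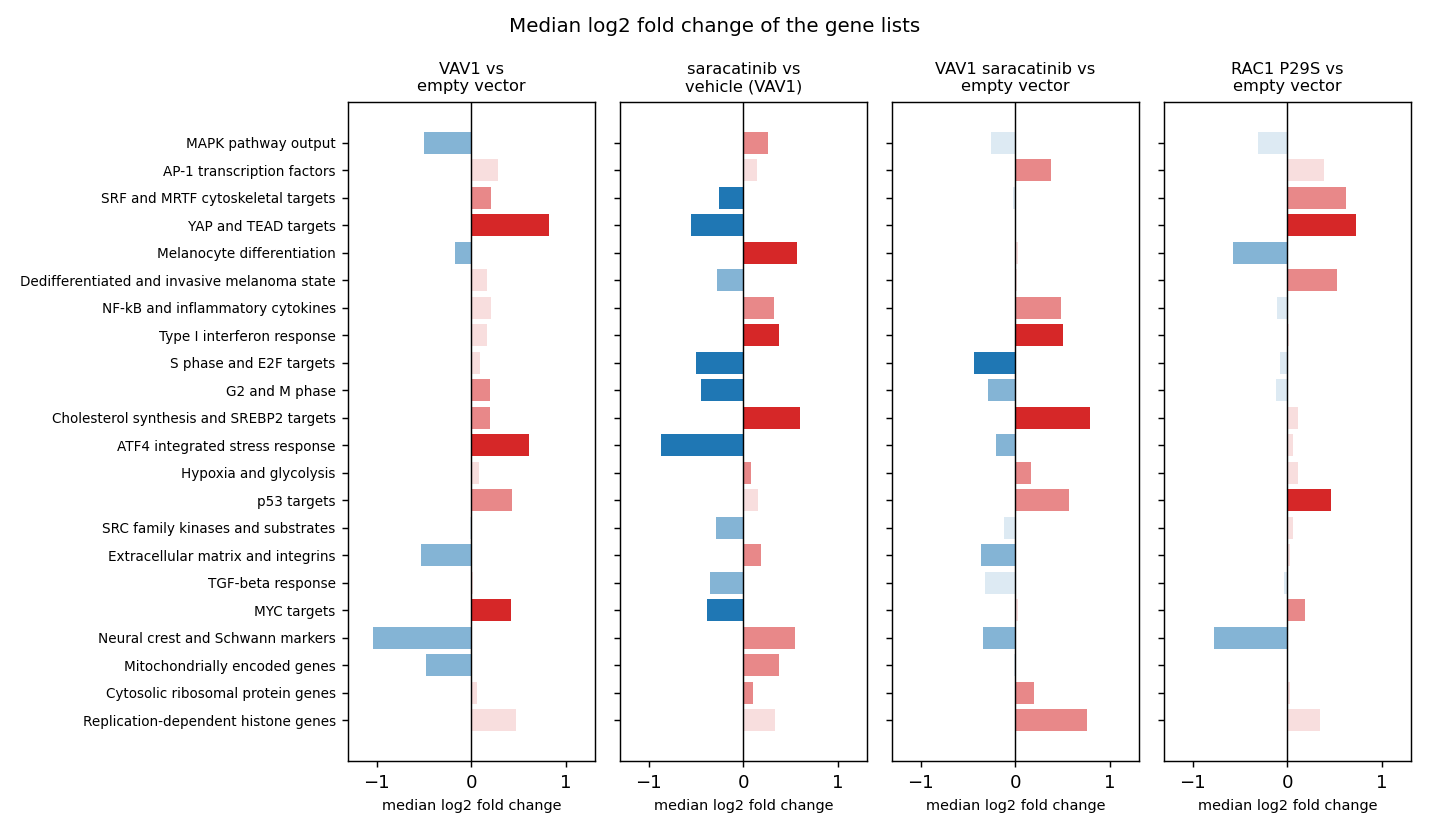
Median log2 fold change (bars) of the 22 gene lists that passed the set test in at least 1 of the 4 comparisons, red for positive and blue for negative medians. Full colour marks lists past the test with a preset and an estimated correlation, medium colour with the preset correlation only, and faint colour lists not past it, and ATF4 targets have a median of 0.61 with VAV1 and -0.87 with saracatinib.

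Of the 6292 genes that VAV1 changed, saracatinib moved 2802 (44.5%) the other way, 439 (6.98%) further the same way, and 3051 (48.5%) did not pass. Several genes named above for 1 of these comparisons were looked up in the other after their values were seen. With saracatinib PDE3A rose by 2.81 ± 0.29, SLC24A3 by 3.11 ± 0.34, SOD3 by 2.29 ± 0.27, RXRG by 2.09 ± 0.28 and FXYD3 by 1.92 ± 0.10 on the log2 scale. Neither BASP1, which differed by -0.26 ± 0.13, nor RGS4 (0.00 ± 0.26, limma adjusted p = 0.995) passed. MME differed by 0.68 ± 0.68 (limma adjusted p = 0.485) and SH3GL2 by 0.22 ± 0.17 (limma adjusted p = 0.347). IL24 rose with VAV1, by 2.21 ± 0.06, and rose further with saracatinib.

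Both comparisons use the VAV1 vehicle libraries, so chance values of those libraries push them apart. In 100 simulations without an inhibitor effect, at most 2 genes moved the other way, and independent lists of these sizes would share 1177 such genes. The simulated count is low by design, since without that effect almost no gene passes for saracatinib. Across genes, which are not independent replicates, the covariance of the fold changes was -0.180 against -0.0294 in the simulations, a difference of -0.151. Of the 5381 genes that saracatinib changed, 2140 (39.8%) were not past the threshold for VAV1. Without an empty-vector group given saracatinib, the data cannot show which of these changes needed VAV1.

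A further comparison sets VAV1 cells with saracatinib against empty-vector cells with vehicle, and so holds the effects of the gene and of the drug. Against that control, 3393 of the 6292 VAV1-changed genes (53.9%) were still changed in the VAV1 direction, 2444 no longer passed, and 455 passed on the other side. The median share of the VAV1 fold change that was left was 58.0% (quartiles 14.8% and 98.5%), against 97.2% in the simulations. Of the 1466 genes that VAV1 changed more than 2-fold, 1094 (74.6%) were still changed in its direction, with a median share of 68.2% left. MME was higher by 7.53 ± 0.68, ANO2 by 6.98 ± 0.48, RGS4 by 6.10 ± 0.26 and BASP1 by 5.99 ± 0.13 on the log2 scale, and the histone copy HIST2H2AA4 was listed at 0 in every control library. The transcription factor ATOH8 (-4.32 ± 0.33), SLC24A2 (-3.41 ± 0.35), IGFBP5 (-3.34 ± 0.14), PKNOX2 (-3.25 ± 0.29) and the cadherin DCHS1 (-3.14 ± 0.24) were lower. The highest limma adjusted p of these genes, the histone copy left out, was 0.000130, for MME.

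In this comparison the YAP and TEAD targets had a median of -0.01, a mean of 0.23 and no set call (camera adjusted p = 0.659), and MYC targets a median of 0.02 (camera adjusted p = 0.959). Members still differed in both directions. Of 22 YAP and TEAD targets, 7 were higher and 5 lower (7 and 5 adjusted over the list alone). Of 29 MYC targets, 8 were higher and 9 lower (9 and 9 adjusted over the list alone). Cholesterol genes lay above the control, with 21 of 24 higher and 0 lower (22 and 0 adjusted over the list alone, median 0.79, camera adjusted p = 2.45e-13). Interferon genes did too, with 16 of 27 higher and 0 lower (18 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 0.000443). S phase genes lay below it, with 26 of 30 lower and 0 higher (0 and 27 adjusted over the list alone, median -0.44, camera adjusted p = 1.34e-11). With an estimated correlation camera gave these 3 lists adjusted p = 0.0121, 0.0435 and 0.0121. A further 10 lists passed with the preset correlation only. G2 and M phase had 23 of 30 lower and 2 higher (2 and 23 adjusted over the list alone, median -0.29, camera adjusted p = 4.75e-07, and adjusted p = 0.0736 with an estimated correlation), and ATF4 targets 13 of 27 lower and 7 higher (7 and 15 adjusted over the list alone, median -0.20, camera adjusted p = 0.0178, and adjusted p = 0.142 with an estimated correlation). Matrix and integrin genes had 24 of 41 lower and 15 higher (16 and 24 adjusted over the list alone, median -0.37, camera adjusted p = 0.0151, and adjusted p = 0.493 with an estimated correlation), and neural crest markers 9 of 18 lower and 5 higher (5 and 10 adjusted over the list alone, median -0.34, camera adjusted p = 0.0262, and adjusted p = 0.118 with an estimated correlation).

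The other 6 of these lists moved up. The p53 targets had 15 of 23 higher and 1 lower (16 and 2 adjusted over the list alone, median 0.56, camera adjusted p = 1.43e-05, and adjusted p = 0.0648 with an estimated correlation), and ribosomal protein genes 52 of 83 higher and 0 lower (53 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 2.21e-09, and adjusted p = 0.430 with an estimated correlation). Replication-dependent histone genes, near-identical copies that can share reads, had 13 of 24 higher and 0 lower (14 and 0 adjusted over the list alone, median 0.76, camera adjusted p = 0.00537, and adjusted p = 0.113 with an estimated correlation). AP-1 factors had 9 of 15 higher and 2 lower (9 and 2 adjusted over the list alone, median 0.38, camera adjusted p = 0.0125, and adjusted p = 0.306 with an estimated correlation), and hypoxia and glycolysis genes 13 of 25 higher and 3 lower (14 and 3 adjusted over the list alone, median 0.16, camera adjusted p = 0.00878, and adjusted p = 0.0736 with an estimated correlation). NF-kB targets and cytokines had 12 of 23 higher and 5 lower (12 and 5 adjusted over the list alone, median 0.48, camera adjusted p = 0.0483, and adjusted p = 0.141 with an estimated correlation). The camera call of that list was lost without VAV1 vehicle 1 (adjusted p = 0.0543), 2 (0.0547) or 3 (0.0512), in a range of 0.0365 to 0.0547 over the 9 libraries, and with quantile normalization (0.0533, range 0.0382 to 0.0533 over the scalings). In all, 6248 genes passed limma, 3222 higher and 3026 lower, 1265 of them more than 2-fold.

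**Figure D3:**
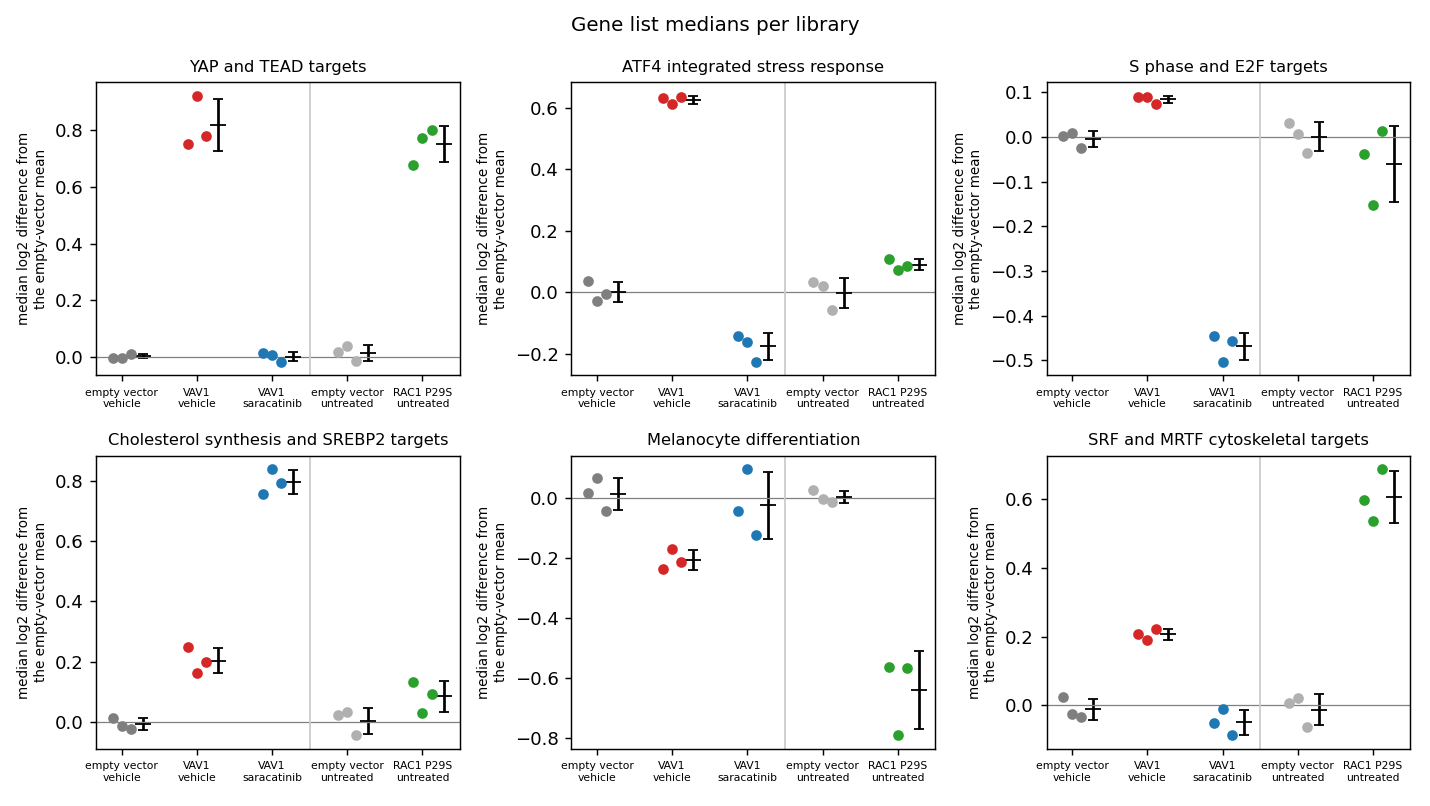
Median over a gene list of the log2 difference from the mean of the matched empty-vector group, in each library (points), with the group mean and SD (black bars, n = 3), for 6 lists and 5 groups. The median fold change of the ATF4 targets was 0.61 with VAV1 and -0.20 with VAV1 and saracatinib, and that of the S phase genes 0.09 and -0.44.

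The RAC1 P29S comparison asks what the activated GTPase did in untreated cells. BASP1 rose by 6.30 ± 0.29 on the log2 scale (SE, 78.9-fold), RGS4 by 5.47 ± 0.18 (44.4-fold), IGFN1 by 5.36 ± 0.31, MME by 4.70 ± 0.21 and the axon guidance gene SEMA5A by 4.52 ± 0.49. CGB8 rose by 5.69 ± 0.50, TRBC2 by 4.55 ± 0.30 and the pseudogene RAC1P2 by 5.14 ± 0.33, all genes whose reads can be shared with near-identical copies, RAC1 itself for the last. The cadherin PCDH15, TRIM51 (-3.98 ± 0.44), SOD3 (-3.73 ± 0.19), RXRG (-3.55 ± 0.20) and PDE3A (-3.45 ± 0.14) were lower. FDCSP (-3.37 ± 0.15), SPRR2D (-3.30 ± 0.28) and SERPINA3 (-3.17 ± 0.05), which encodes antichymotrypsin, were lower too. The highest limma adjusted p of these 16 genes was 0.000498, for PCDH15.

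Cytoskeletal, YAP and TEAD, and p53 target genes rose with RAC1 P29S. Of 25 SRF and MRTF targets, 21 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.62, camera adjusted p = 9.16e-13, and adjusted p = 0.168 with an estimated correlation). TPM1 rose by 1.05 ± 0.05, TPM4 by 0.81 ± 0.04 and FLNA by 0.61 ± 0.04. Of 22 YAP and TEAD targets, 17 rose and 2 fell (18 and 2 adjusted over the list alone, median 0.73, camera adjusted p = 8.55e-09), with ANKRD1 at 3.57 ± 0.10 and CYR61 at 1.79 ± 0.07. Of 23 p53 targets, 17 rose and 0 fell (17 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 7.50e-09), with GDF15 at 4.28 ± 0.14 and BAX at 0.82 ± 0.06. With an estimated correlation camera gave both lists an adjusted p of 0.0354. Of 24 genes of the dedifferentiated and invasive state, 15 rose and 5 fell (15 and 5 adjusted over the list alone, median 0.52, camera adjusted p = 1.85e-05, and adjusted p = 0.0625 with an estimated correlation). The nerve growth factor receptor NGFR rose by 1.98 ± 0.08 and TGFBI by 1.60 ± 0.05, while TNC changed by -1.44 ± 0.06. Of 29 MYC targets, 17 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 3.04e-06, and adjusted p = 0.184 with an estimated correlation).

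Melanocyte and neural crest genes fell with RAC1 P29S. Of 15 melanocyte differentiation genes, 8 fell and 1 rose (1 and 9 adjusted over the list alone, median -0.57, camera adjusted p = 0.000345, and adjusted p = 0.0934 with an estimated correlation). Of 18 neural crest and Schwann markers, 10 fell and 6 rose (6 and 10 adjusted over the list alone, median -0.77, camera adjusted p = 0.0381, and adjusted p = 0.194 with an estimated correlation). TFAP2B changed by -3.00 ± 0.07, ERBB3 by -1.61 ± 0.06 and SOX10 by -1.10 ± 0.05, and MITF rose by 1.23 ± 0.11. MAPK pathway output did not pass, with 13 lower and 5 higher of 20 (5 and 13 adjusted over the list alone, median -0.32, camera adjusted p = 0.0638, range 0.0425 to 0.0881 without 1 of the 6 libraries), with SPRY4 at -1.77 ± 0.05 and EPHA2 at 1.51 ± 0.05. ATF4 targets had a median of 0.06 (camera adjusted p = 0.394) and S phase genes a median of -0.07 (camera adjusted p = 0.0964, range 0.0425 to 0.322 without 1 of the 6 libraries). In all, 4369 of 14036 genes passed limma, 2194 higher and 2175 lower, 1057 of them more than 2-fold. The camera call of the neural crest list was lost without empty vector 1 (adjusted p = 0.0607) and 3 (0.0704), in a range of 0.0201 to 0.0704 over the 6 libraries, and under total-count scaling (0.0543, range 0.0256 to 0.0543 over the scalings).

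Markers of other cell types gave no set call in any of these 4 comparisons. Haematopoietic, fibroblast, epithelial and endothelial markers had camera adjusted p = 0.804, 0.640, 0.640 and 0.746 with VAV1, over 7, 7, 5 and 7 tested genes. In each, 2 rose, and 1, 1, 2 and 1 fell. Adjusted over the list alone the counts were the same but for 2 lower fibroblast markers. With RAC1 P29S none of these lists passed, and haematopoietic and endothelial markers had camera adjusted p = 0.547 and 0.545. Median and mean differed in sign for endothelial markers with VAV1 (-0.11 and 0.29) and with RAC1 P29S (-0.18 and 0.49), and for haematopoietic (-0.02 and 0.33) and fibroblast markers (-0.13 and 0.28) with RAC1 P29S. With VAV1 the macrophage marker CD68 changed by 1.21 ± 0.06, LYZ by -2.11 ± 0.14, KRT18 by 1.10 ± 0.05 and POSTN by 4.32 ± 0.52.

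VAV1 and RAC1 P29S changed many genes in the same direction, each against its own empty-vector libraries. Among the 13810 genes tested in both, 1505 rose in both and 1412 fell in both, against 516 and 441 for independent lists of those sizes, and 150 moved in opposite directions, against 956. The 2917 genes of the same direction were 67.4% of the RAC1 P29S calls and 47.8% of the VAV1 calls. Ranked by the smaller of the 2 changes, BASP1, RGS4, IGFN1, MME and VSTM1 (5.18 ± 0.60 with VAV1 and 4.49 ± 0.34 with RAC1 P29S) led the shared rises. SOD3, RXRG, PDE3A, SERPINA3 and TFAP2B led the shared falls, with SERPINA3 at -3.32 ± 0.05 with VAV1. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.739 and Spearman's rho 0.580.

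**Figure D4:**
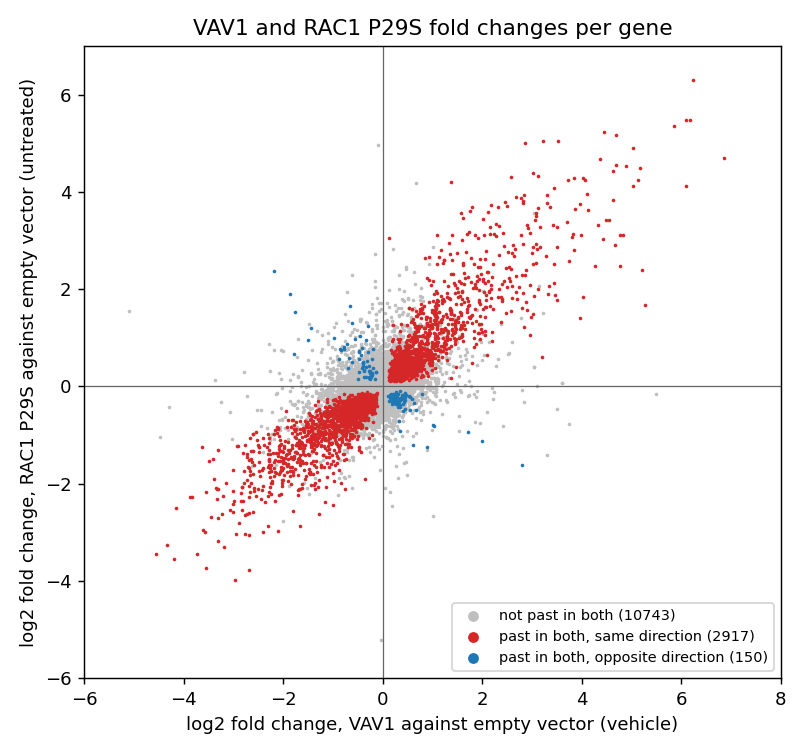
Log2 fold change with VAV1 (x axis, vehicle) against that with RAC1 P29S (y axis, untreated) for the 13810 genes tested in both comparisons (points). Red marks the 2917 genes past the threshold in both with the same direction, blue the 150 with opposite directions and grey the rest.

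The effects of VAV1 and RAC1 P29S differed for 2188 genes by a limma test of the difference itself. SH3GL2 rose by 5.50 ± 0.17 with VAV1 and differed by -0.17 ± 0.25 with RAC1 P29S (difference 5.66 ± 0.27, limma adjusted p = 7.47e-10). ASTN1 and FBXL7 were also higher in the VAV1 effect, by 3.98 ± 0.36 and 3.10 ± 0.37, and CERS4 and ADAMTS4 lower, with differences of -2.55 ± 0.43 and -2.63 ± 0.58. ATF4 targets were higher in the VAV1 effect for 16 of 27 genes and lower for 1 (19 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 8.66e-13). G2 and M phase genes were higher for 20 of 30 and lower for 0 (23 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 3.15e-09), and MYC targets for 14 of 29 and 1 (15 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 1.71e-05). SRF and MRTF targets were lower in the VAV1 effect for 15 of 25 genes and higher for 1 (1 and 17 adjusted over the list alone, median -0.34, camera adjusted p = 1.76e-09), and MAPK pathway output for 12 of 20 and 2 (2 and 12 adjusted over the list alone, median -0.34, camera adjusted p = 1.10e-08). With an estimated correlation camera gave these 5 lists adjusted p = 0.0107, 0.0108, 0.0207, 0.0207 and 0.0207. YAP and TEAD targets gave no call for the difference (median -0.11, camera adjusted p = 0.189). Of the 2188 genes, 51.4% were higher in the VAV1 effect, against 40.2% with upper-quartile scaling. Vehicle and experiment differ between the arms. The set test on this contrast was added after the data were seen.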

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

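The set test on the difference of effects, the test of its scaling and the comparison of RAC1P2 with RAC1 were chosen after the result was seen. The tests of splits, simulations, exclusions and windows had their outcomes written down before they were run, but after the counts and overlaps were known. Where a test is said below not to decide, that reading was not part of these outcomes.

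The effects of VAV1 and RAC1 P29S, measured against separate control libraries, differed for 2188 genes by limma. The log2 difference, VAV1 minus RAC1 P29S, was 5.66 for SH3GL2, 3.98 for ASTN1, 3.53 for SPANXA1, 3.53 for SPANXA2 and 3.10 for FBXL7. It was -2.94 for the pseudogene SLC2A3P1, -2.67 for the readthrough gene ST20-MTHFS, -2.63 for ADAMTS4 and -2.55 for CERS4. SPANXA1 and SPANXA2 have identical values in every library, and reads of SLC2A3P1 can come from its parent gene. For 12 lists the set test on the difference passed, with medians of -0.34 for MAPK pathway output, -0.34 for SRF and MRTF targets, -0.23 for the dedifferentiated state, 0.16 for S phase, 0.25 for G2 and M phase and 0.57 for ATF4 targets. The others were -0.13 for p53 targets, -0.38 for matrix and integrins, 0.18 for MYC targets, -0.29 for receptor tyrosine kinases, -0.43 for neural crest markers and -0.47 for mitochondrially encoded genes. With an estimated correlation the S phase, p53, receptor tyrosine kinase and mitochondrial lists did not pass, at camera adjusted p = 0.125, 0.0758, 0.125 and 0.403.

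Of 100 splits of the libraries within the 2 experiments, 6 gave at least 2188 differing genes, the real split included, and the highest other gave 6751. The other 5 splits each kept the real groups of 1 or both experiments and so carried a whole effect into the difference, which points to the structure of the samples, so this share does not decide on chance. That reading was set after the count was known. By the outcome written down before, 6 of 100 would have gone with chance. The 82 splits that mixed the groups of both gave 0 genes each. Mixing puts the real group differences into the spread, so these counts do not bear on chance either. A factor common to an experiment cancels in the difference. Under 4 other scalings 87.1% to 95.7% of the 2188 genes stayed past the threshold with the same sign. That argues against the choice among these scalings as the whole cause. Each of them levels totals or the bulk of genes between libraries, so they could not show a shift of most genes. Vehicle and experiment also differ between the arms, and no library separates these from the genes, so a biological difference stays open as untested.

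The overlap of 2917 genes was not reached by other splits: 1 of 100, the real one, gave as many, and the highest other gave 150. That other split kept the groups of both experiments and turned 1 of them, so it counts the genes of opposite direction. Splits that mix the groups of an experiment call no genes there, which fixes their shared count at 0. This share therefore does not decide on chance. Copy number differences between the cell populations were tested by removing the median fold change of each 10 Mb window. Of the VAV1 calls in those windows 84.8% stayed past the threshold, and of the RAC1 P29S calls 90.8%. By the outcome written down before, that argues against differences spanning whole windows as the whole cause. Smaller gains or losses would not be removed, and the overlap was not counted again after the correction. Window medians ranged from -0.318 to 0.582 for VAV1 and from -0.212 to 0.367 for RAC1 P29S. Window medians still spread more than in shuffled genomes, with an SD of 0.122 against at most 0.0948 for VAV1 and 0.0760 against 0.0732 for RAC1 P29S, so copy number may contribute to some changes. A response common to the 2 genes stays open, as do selection during the making of the lines and clonal differences, which the design does not separate. The titles mark both controls as empty vector, without saying whether they came from 1 population. A trait of such a shared control would enter both comparisons in the same direction, which the expectation for independent lists leaves out.

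The 2802 opposite moves under saracatinib were reached in 1 of 100 assignments of the 9 libraries, the real one, and the highest other gave 2460. That assignment kept every library with its own group and exchanged the roles of the groups. Other such exchanges, which were not drawn, would reach the count. Exchanging empty vector and saracatinib only turns both contrasts and gives 2802 again. With the empty vector as the shared group, the count is the 3393 genes changed the same way against it. The share thus depends on the draw and does not decide on chance. The shared VAV1 vehicle libraries gave at most 2 such genes in 100 simulations. These held no inhibitor effect, so almost no gene passed for saracatinib. That count cannot show how far the shared libraries tilt 2802 opposite against 439 same moves. The covariance of the fold changes, -0.180 against -0.0294 in the simulations, argues against them as the whole cause. With the cell cycle, MYC, ATF4 and ribosomal lists left out, the ratio of opposite to same moves was 6.36, against 6.38 with all genes. Those lists hold 1.62% of the VAV1-changed genes, too few for this bound to decide on slower proliferation. The outcome written down before held no such condition, and by it the ratio would have argued against slower proliferation alone. An inhibitor effect that does not depend on VAV1 stays open, because no empty-vector group received saracatinib. The 2140 genes that saracatinib changed and that had not passed for VAV1 lie outside the 2802. Without that group they cannot show whether the opposite moves needed VAV1.

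For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave the highest count for VAV1 (6292 genes, highest other 0; 12 lists, highest other 8), for saracatinib (5381, highest other 1; 19 lists, highest other 12) and for VAV1 with saracatinib (6248, highest other 1; 13 lists, highest other 9). It did so for RAC1 P29S genes too (4369, highest other 0). For RAC1 P29S lists, 4 of 10 splits gave at least the 7 of the real split, and the highest other gave 9. Every other split mixes the real groups, so their difference enters the spread and leaves almost no gene past the threshold. The list counts of such splits still hold part of the real difference. None of these counts therefore decides on chance.

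The rise of RAC1P2 with RAC1 P29S could come from reads of the transgene. Its log2 ratio to RAC1 was -4.94 ± 0.05 (SD, n = 3) with RAC1 P29S and -7.03 ± 0.80 in the control, a difference of 2.09. A fixed share of RAC1 reads would leave the ratio unchanged, but the transgene can share another part of its sequence with the pseudogene than the endogenous gene does. The 2 sources cannot be told apart.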

How the results depend on the processing

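The pseudocounts, total-count scaling, quantile normalization, upper-quartile scaling for lists and the Spearman correlation were chosen after seeing the data. TMM scaling, the DESeq2 Wald test and limma-voom were planned and not run, because the values are not counts. Under recomputed, upper-quartile and total-count scaling, quantile normalization, both filters, both pseudocounts and the replicate block, each count of changed genes, the shared count and the opposite-move count stayed within 1.5 times its value. The largest shift of the median of all genes under these settings was 0.04 (log2).

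Against a fold change of 1.5, limma gave 1171 genes for VAV1, 488 for saracatinib (74.6% higher, against 48.9%), 897 for VAV1 with saracatinib (62.9% higher, against 51.6%) and 801 for RAC1 P29S, fewer because small changes no longer count. With an estimated correlation 3, 9, 3 and 2 lists passed in these comparisons, against 12, 19, 13 and 7. With fry, which does not compare a list with other genes, it was 25, 24, 25 and 20. The correlation of the VAV1 and RAC1 P29S changes was 0.796 with the stricter filter, 0.757 with a pseudocount of 16 and 0.580 as Spearman's rho, against 0.739. The cause was not tested.

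Without 1 library the counts ranged from 5408 to 6262 for VAV1, 4563 to 5460 for saracatinib, 5344 to 6236 for both, 3426 to 4134 for RAC1 P29S, 1697 to 2169 for the difference, 2452 to 2910 shared and 2328 to 2685 opposite. The correlation ranged from 0.721 to 0.735, and the lists from 11 to 14, 18 to 20, 12 to 14 and 6 to 9. Replicate numbers do not pair the libraries, and with them as a replicate block the VAV1 effect minus RAC1 P29S effect: genes that differ numbered 1746.

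For 360 pairs of a named gene and a comparison, 5499 alternative values were computed: 5421 kept direction and side of the threshold, 74 lost the threshold, 4 gained it and 0 reversed. They affect 21 pairs, with RAC1 in the VAV1 comparison (11 values), MT-ATP6 (7) and SLC2A3P1 (6) first. Low counts limit what the log scale shows, since a pseudocount of 1 understates their folds.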

Other observations

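All of the following was chosen after the data were seen. Genes were grouped by the letters of their symbol into 176 families of at least 10 tested genes (170 for RAC1 P29S). Of 17 HLA genes, 15 fell with VAV1 and 0 rose (median -1.60; camera adjusted p over the families = 7.42e-13, and adjusted p = 0.165 with an estimated correlation). With saracatinib 14 of 17 rose and 0 fell (median 0.79; camera adjusted p = 4.62e-09, and adjusted p = 0.185 with an estimated correlation). With RAC1 P29S 15 of 18 fell and 0 rose (median -1.27; camera adjusted p = 1.64e-13, and adjusted p = 0.991 with an estimated correlation). The medians had the same sign under the 4 other scalings. HLA genes share reads, so their values are not independent. Genes with no close copy moved as well: CD74, the invariant chain of class II molecules, changed by -1.98 ± 0.05 with VAV1, 0.64 ± 0.05 with saracatinib and -1.23 ± 0.06 with RAC1 P29S. CIITA, the class II transactivator, changed by -1.91 ± 0.14, 0.65 ± 0.14 and -0.70 ± 0.06. B2M differed by 0.02 ± 0.06 with VAV1 (limma adjusted p = 0.850) and changed by 0.90 ± 0.06 and -0.36 ± 0.04 with saracatinib and RAC1 P29S. The window of chromosome 6 from 30000001 to 40000000, with 165 genes, had a median of -0.03 with VAV1. Some of these genes also differed between the empty-vector groups of the 2 experiments, which were scaled separately. HLA-DQA1 lay at 10.13 ± 0.02 (SD, n = 3) with vehicle and 12.21 ± 0.04 untreated, and CIITA at 10.07 ± 0.12 and 11.20 ± 0.10. HLA-DOA differed little, at 7.71 ± 0.18 and 7.80 ± 0.26. Levels thus varied without either transgene, and the cause was not tested.

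Of 10 integrin alpha genes, 8 fell with VAV1 (median -1.09; camera adjusted p = 0.00121, and adjusted p = 0.473 with an estimated correlation) and 9 rose with saracatinib (median 0.91; camera adjusted p = 5.48e-05, and adjusted p = 0.238 with an estimated correlation). With RAC1 P29S 2 of 10 rose and 3 fell (median 0.02, camera adjusted p = 0.926). Of 49 mitochondrial ribosomal protein genes with symbols in MRPL, 32 rose with VAV1 and 0 fell (median 0.24; camera adjusted p = 2.64e-05, and adjusted p = 0.683 with an estimated correlation). With saracatinib 2 rose and 13 fell (median -0.08) and with RAC1 P29S 13 rose and 1 fell (median 0.12), neither past camera. These medians of both families had the same sign under the 4 other scalings.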
